A study of Homo sapiens with 52 samples.

How the data were processed

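RNA of PC9 and HT29 cells was sequenced in 52 libraries, 3 or 4 for each of 16 groups. Per the labels' protocols, cells grew in DMEM with 10% FBS, siRNA pretreatment lasted 2 days, total RNA was taken with RNeasy columns, and TruSeq stranded total RNA libraries were made. Per the submitters' processing notes, the authors trimmed reads with Trim Galore 0.5.0, aligned them to hg38 with STAR 2.7.5a, used Picard, and counted with RSEM. The deposited values used here are RSEM expected counts per gene, which the authors made by sharing reads that match several genes among them. Values of 452 to 2523 genes per library had a fractional part, with no tolerance allowed, and all were rounded before testing.

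The table held 60662 gene records and 92 ERCC spike-ins, which stayed out of library sizes and tests. Among the gene records 45 were copies from the Y pseudoautosomal region and 1768 shared a symbol with another record. Genes kept the identifiers given with the counts, and GENCODE v29 supplied gene positions, matched by symbol. Reads were not used here, so alignment and counting were not repeated. All 60 pairs of replicates within groups were compared for copies; the lowest chi-square per degree of freedom was 2.66, so none was a copy; pairs across groups were not compared. Libraries were grouped by the labels, and none was left out of the tests first made. The 36 treatment and siATF4 set libraries and the 16 siBAX/BAK and knockout libraries differ in composition, so tests that cross the 2 kinds were made only on differences of A/S effects.

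Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood F test), with 1 fit for the 4 groups of each set, on PC9 treatments, HT29 treatments, siATF4 and siBAX/BAK with knockout. Differences of A/S effects between sets were fitted on their 4 groups. A gene was called, and is said to have risen or fallen, at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested; higher and lower counts are of such genes. Log2 changes are edgeR estimates, and the SE is the absolute change divided by the root of F. CPM values (counts per 1e6 counts) are means with SD after TMM scaling. For fixed lists, camera (limma 3.58.1) was run with a preset correlation of 0.01 between genes, over the lists measured, and again with a correlation estimated from the residuals; fry was the other list test. The 29 lists hold 543 entries, of which 540 matched a symbol, and were fixed with the main tests and alternatives before the data were examined. Counts of list members are given over all genes and adjusted over the list alone.

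Genes are named by a rule. ATF4, DDIT3, ATF3, TRIB3, ASNS, CHAC1, BAX, BAK1, BOK, BCL2, BCL2L1, MCL1, DUSP6, MKI67 and CDKN1A could always be named. The 5 largest rises and the 5 largest falls were taken among called protein-coding genes with a mean of at least 5 CPM whose libraries did not overlap between the groups, a condition not used for differences of effects. From a fixed list up to 4 called members were taken by p, or the member of smallest p where none was called. EGFR, CDH1, EPCAM, KRT8 and VIM come from the fixed epithelial and mesenchymal lists or from the line's driver; IRS4, LIN28B and RN7SL1 were chosen after their values were seen. Some genes under this rule are not reported here.

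The alternatives chosen before the data were examined were DESeq2 size factors within edgeR, no low-count filter, a DESeq2 1.42.0 Wald test, replicate number as a block, a fit of only the 2 groups compared, and each library left out in turn. Alternatives added after the first results were libraries over 10% mitochondrial mRNA left out, the mitochondrial mRNA share as a covariate, the share of the siBAX/BAK-like profile as a covariate, and protein-coding genes only. That profile is 104 protein-coding genes with a group mean above 30 CPM in the libraries labelled siBAX/BAK without A/S and below 1.5 in PC9 DMSO and in the knockout, and its share is the median over them of a library's level divided by that group mean. Replicate numbers were checked for pairing by correlating residuals of libraries of the same number. Of the same-number pairs, 5 of 18 in PC9, 0 of 18 in HT29, 10 of 18 in the siATF4 set and 0 of 24 in the siBAX/BAK and knockout set passed 0.1, so the numbers were not taken as pairs. All 3 passed it for siNT with siATF4 (0.64, 0.72 and 0.576) and for erlotinib with paclitaxel (0.155, 0.194 and 0.461). With the block edgeR called 16 genes for siATF4 against siNT in place of 11 and camera 10 lists in place of 9.

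The tests were tried on simulated data in which 80 genes were changed 4-fold, 60 genes 2-fold and 60 genes 1.5-fold at the spread and depth of the real libraries. In the PC9 A/S comparison edgeR recovered 85.0%, 33.3% and 1.67% of them, with 3 false calls among 16578 genes. In HT29 A/S it recovered 96.2%, 91.7% and 83.3%, in siATF4 against siNT 10%, 0% and 0%, and in the difference between knockout and siBAX/BAK 93.8%, 91.7% and 78.3%. A count of 0 in the siATF4 set therefore carries little weight. DESeq2 made 33 false calls for PC9 A/S and 39 for siATF4, where edgeR made 3 and 0. Overlaps were compared with the product of the 2 call rates. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 was used to load the counts and draw the figures.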

Results

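The data are 52 RNA sequencing libraries from 2 human cancer cell lines. PC9 is a lung adenocarcinoma line driven by an activating EGFR mutation, and HT29 is a colorectal adenocarcinoma line driven by mutant BRAF. The labels' A/S stands for ABT737, which blocks the anti-apoptotic proteins BCL-2 and BCL-XL, given with S63845, which blocks MCL-1. The series title sets parental cells against persister cells, meaning cells that outlive a drug that kills most of their population. The libraries form 16 groups, of which 12 hold 3 libraries and 4 hold 4. PC9 received DMSO, erlotinib, paclitaxel or A/S, and HT29 received DMSO, irinotecan, vemurafenib or A/S. PC9 pretreated with non-targeting siRNA (siNT) or siRNA against ATF4 (siATF4), and groups of 4 labelled siBAX/BAK or BAX/BAK/BOK triple knockout (TKO), were each sequenced without and with A/S.

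Total counts per library, in units of 1e6, ran from 32.3 to 40.0 for PC9 DMSO, 23.1 to 34.3 for erlotinib, 13.2 to 19.6 for paclitaxel and 19.4 to 54.1 for PC9 A/S. In HT29 they ran from 34.1 to 43.5 for DMSO, 15.8 to 23.1 for irinotecan, 27.8 to 29.5 for vemurafenib and 30.8 to 42.5 for A/S. They were 14.3 to 30 for siNT, 13.6 to 23.2 for siNT with A/S and 9.37 to 38.8 for siATF4, while siATF4 with A/S reached 23.0 but had 0.88 in library 1. The deepest were the groups of 4, with 46.0 to 55.0 for siBAX/BAK, 46.3 to 128 for siBAX/BAK with A/S, 33.4 to 72.7 for the knockout and 55.1 to 101 for the knockout with A/S. These 16 also differed in composition from the other 36: RN7SL1, an abundant small cytoplasmic RNA, took at most 0.002% of their counts against 0.55% to 7.70% elsewhere, and their ERCC spike-in share was 3.66% to 7.62% against 0% to 4.58%. In siNT library 2, siATF4 library 2 and siATF4 A/S libraries 1 and 2, mitochondrially encoded mRNAs took 15.8%, 15%, 16.7% and 20.1% of the counts, against 3.49% or less in the other 48. The labels do not say that replicates came from separate cultures, so they may be technical.

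**Figure D1:**
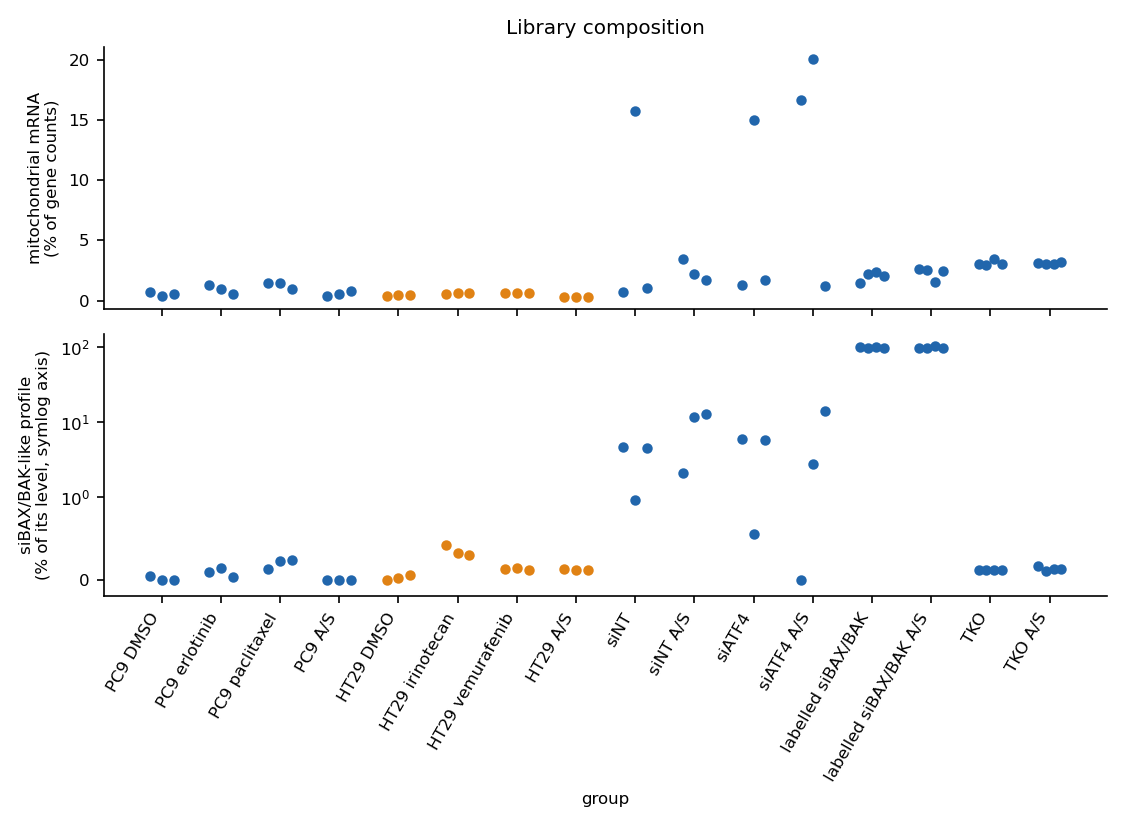
Share of counts in mitochondrially encoded mRNAs (percent) and share of the siBAX/BAK-like profile (percent, linear near 0 and logarithmic above) for each library by group. The 4 libraries with between 15% and 20.1% mitochondrial mRNA all lie in the siNT and siATF4 groups.

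The genes aimed at were ATF4 (ENSG00000128272.14, chromosome 22, 39519695 to 39522685, plus strand, GRCh38), BAX (ENSG00000087088.20, chromosome 19, 48954815 to 48961798, plus strand), BAK1 (ENSG00000030110.13, chromosome 6, 33572547 to 33580293, minus strand) and BOK (ENSG00000176720.6, chromosome 2, 241551424 to 241574138, plus strand). ATF4 is the transcription factor of the integrated stress response, and BAX, BAK1 and BOK encode proteins that permeabilise the outer mitochondrial membrane. ATF4 mRNA was 67.7 ± 2.42 CPM (counts per 1e6 counts; SD, n = 3) under siATF4 and 258 ± 29.2 under siNT. With A/S added it was 94.2 ± 14.9 and 317 ± 9.58 (SD, n = 3 each). In the libraries labelled siBAX/BAK, BAX stood at 43.3 ± 2.55, BAK1 at 21.9 ± 0.923 and BOK at 1.11 ± 0.201 CPM (SD, n = 4), which is 0.550, 0.570 and 0.0240 times the siNT means. In the knockout the means were 64.9 ± 1.97 for BAX, 68.7 ± 2.61 for BAK1 and 19.7 ± 0.256 for BOK (SD, n = 4), or 1.16, 1.97 and 0.503 times PC9 DMSO. These ratios cross library kinds and were not tested, and mRNA level does not report whether an edited gene makes protein.

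**Figure D2:**
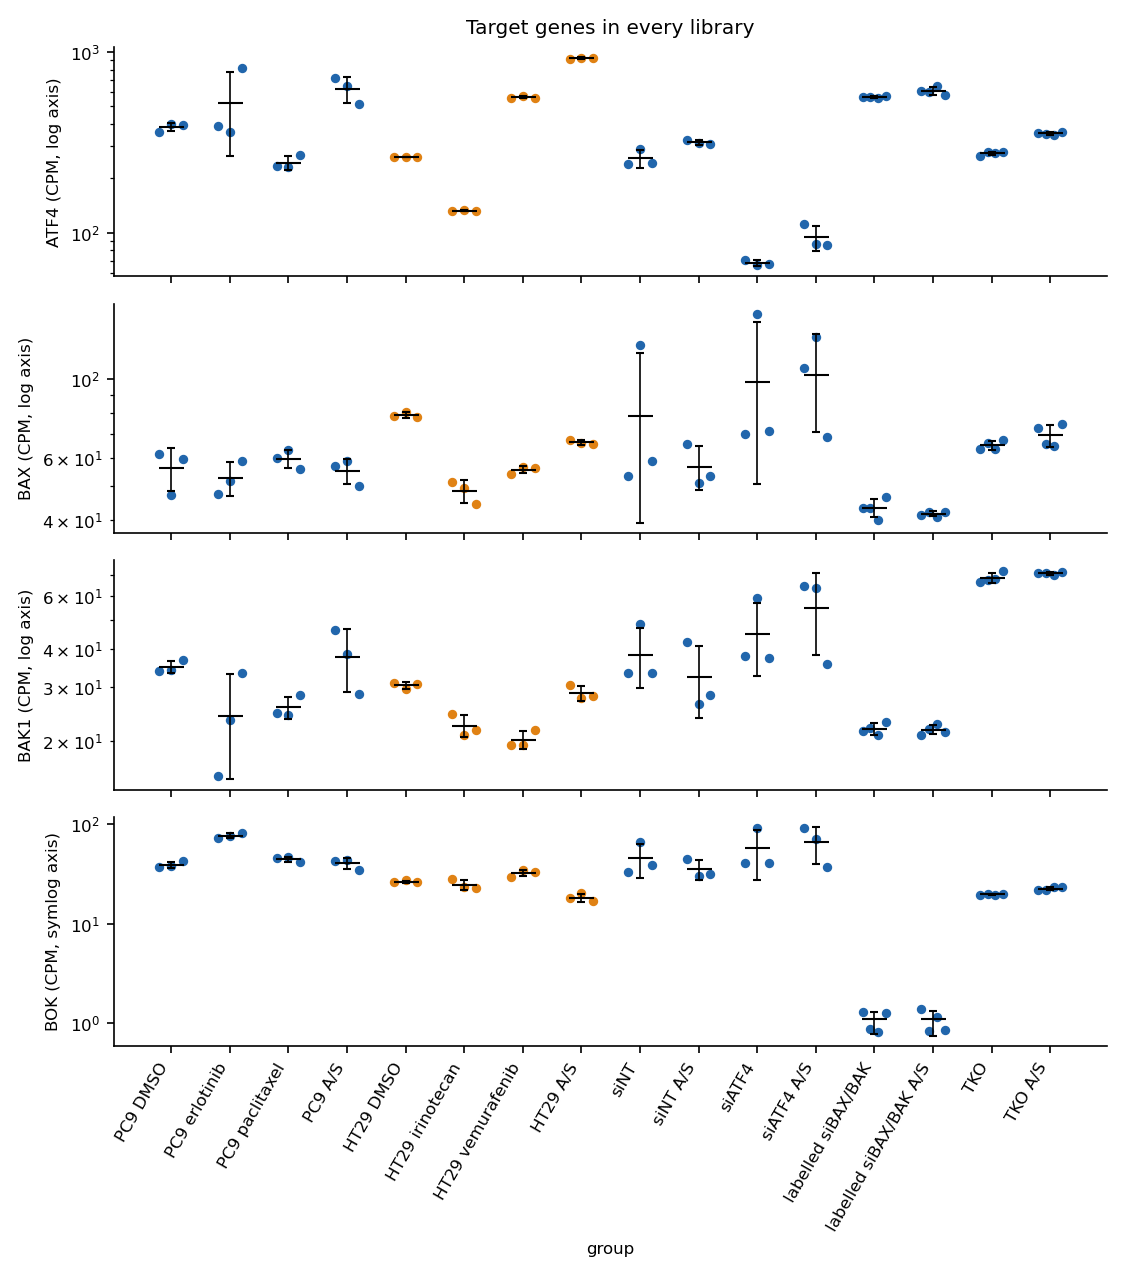
CPM of ATF4, BAX, BAK1 and BOK in every library (points, logarithmic axes, linear near 0 for BOK) with the group mean and SD in black, PC9 in blue and HT29 in orange. ATF4 is lowest in the siATF4 groups, at 67.7 and 94.2 CPM.

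The libraries labelled siBAX/BAK differed from every other PC9 group in genes other than their targets. EGFR stood at 17.2 ± 1.60 CPM (SD, n = 4) against 1350 ± 1.22 in PC9 DMSO (n = 3) and 630 ± 22.7 in the knockout (n = 4). Of 19 epithelial genes above 5 CPM in a group, 17 lay below 25% of their level in every other PC9 group, such as the adhesion gene CDH1 with 5.15 ± 0.401 against 299 ± 5.98 in PC9 DMSO. Across 12575 genes, which are not independent replicates, Pearson's r with PC9 DMSO was 0.622 for these libraries, 0.917 for siNT, 0.897 for the knockout and 0.751 for HT29 DMSO. Every comparison below that uses the siBAX/BAK label carries this difference.

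Erlotinib inhibits the EGFR kinase, and its comparison with DMSO asked how PC9 cells under the drug against their driver differ from untreated cells. Cell cycle, ERK output and cholesterol synthesis genes fell together, and targets of the integrated stress response and ATF4 rose. All 24 measured G1/S genes fell, such as TYMS (log2 change -1.92 ± 0.18 SE) and MCM7 (-1.24 ± 0.13). All 26 G2/M genes fell, among them the proliferation marker MKI67, from 723 ± 58.1 to 192 ± 49.0 CPM (SD, n = 3 each). With an estimated correlation the G1/S list had adjusted p = 0.295 and the G2/M list adjusted p = 0.371. Of 19 ERK output genes 12 fell and 1 rose, and DUSP6, an ERK phosphatase that ERK induces, changed by -3.16 ± 0.52 (adjusted p = 0.371 with an estimated correlation for the list). Of 21 cholesterol synthesis genes 20 fell, such as HMGCS1 (-1.98 ± 0.19), and all 11 replication-dependent histone genes fell (adjusted p = 0.371 with an estimated correlation for both). Among 44 stress response and ATF4 targets 30 rose and 2 fell: NUPR1 changed by 5.98 ± 0.33, CHAC1 by 3.48 ± 0.20 and ASNS by 2.43 ± 0.32 (adjusted p = 0.295 with an estimated correlation). ATF4 mRNA itself was not called at 0.45 ± 0.27. Of 11 pro-apoptotic BCL-2 family genes 5 rose, including the BH3-only genes BMF (3.52 ± 0.28) and HRK (3.33 ± 0.42), though the list's median was -0.09 with a mean of 0.82 (adjusted p = 0.371 with an estimated correlation), and BCL2 fell by 1.15.

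In the same comparison 7 of 12 antigen presentation genes rose, such as TAPBP and HLA-B, as did 8 of 20 NF-kB and inflammatory genes with 2 lower (IL6 2.90 ± 0.38), with adjusted p = 0.584 and adjusted p = 0.658 with an estimated correlation. NRF2 targets (2 higher and 10 lower of 18), heat shock genes (1 and 5 of 11), nuclear OXPHOS genes (15 lower of 29) and cytosolic ribosomal proteins (4 lower of 33) were lower as lists, with adjusted p = 0.518, 0.371, 0.658 and 0.665 with an estimated correlation. Adjusted over the list alone, the counts were 31 higher for ATF4 targets, 14 lower for ERK output, 10 higher for NF-kB genes and 0 for ribosomal proteins, and as given for the other lists. The 5 largest rises were in IGFBP5, NUPR1, DCLK2, IQCN and TAGLN (log2 4.91 to 6.03) and the 5 largest falls in FAT2, PTHLH, HIST1H4I, HIST1H4L and CNTN1 (-3.86 to -3.41). In all, edgeR called 8329 of 19151 genes, 4788 higher and 3541 lower, of which 5004 changed at least 2-fold. Camera called 13 lists and 0 with an estimated correlation (fry called 16). Erlotinib library 3 stood apart, with 1.98% of counts in lncRNA against 4.39% and 6.32% (DMSO mean 1.33%) and ATF4 at 814 CPM against 360 and 389, and the count was 5111 without DMSO library 2 and 5188 in a fit of the 2 groups. Without erlotinib library 3 camera lost the pro-apoptotic, antigen presentation and NF-kB lists (adjusted p = 0.146, 0.0895 and 0.0588), and without erlotinib library 2 the heat shock list (0.058).

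Paclitaxel stabilises microtubules and arrests dividing cells in mitosis. PC9 cells under paclitaxel differed from DMSO in 62.7% of the genes tested, with cell cycle, ribosomal, OXPHOS and cholesterol synthesis genes lower and inflammatory genes higher. All 26 G2/M genes fell, such as the motor gene KIF11 (-1.88 ± 0.28) and CENPF (-1.57 ± 0.23), and 19 of 24 G1/S genes, such as MCM6 (-2.17 ± 0.22); both lists had adjusted p = 0.646 with an estimated correlation. All 33 cytosolic ribosomal proteins and 28 of 29 nuclear OXPHOS genes fell (adjusted p = 0.812 and adjusted p = 0.786 with an estimated correlation), while on average lncRNA took 4.30% of counts against 1.33% in DMSO, mitochondrial mRNAs 1.30% against 0.548%, and 26122 genes were detected against 23051. Of 20 NF-kB and inflammatory genes 17 rose, such as the cytokines IL6 (4.32 ± 0.39) and LIF (2.17 ± 0.21). Of 21 cholesterol synthesis genes 17 fell, as did 13 of 18 NRF2 targets, such as AKR1B10 (-2.90) and GCLC (-1.71), with 1 higher, and all 11 histone genes; these 4 lists had adjusted p = 0.646 with an estimated correlation. Of 15 mitochondrial chaperones and proteases 10 fell and 1 rose (adjusted p = 0.812 with an estimated correlation). ATF4 targets went both ways, 15 higher and 17 lower of 44, with a median of -0.25 and a mean of 0.24, and the list was not called (camera adjusted p = 0.490); PPP1R15A, ATF3 and DDIT3 changed by 2.69 ± 0.18, 2.40 ± 0.17 and 2.35 ± 0.19.

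The cell cycle inhibitor CDKN1A rose under paclitaxel (1.25 ± 0.42) and so did BCL2L1, which encodes BCL-XL (0.62 ± 0.16), while BCL2 fell by 0.86. CDKN1A lost its edgeR call without DMSO library 1, 2 or 3 or paclitaxel library 1 or 2 (adjusted p = 0.0536 to 0.0715). The largest rises were AC006064.6, which had 0 counts in all 3 DMSO libraries and 15.1 ± 7.67 CPM under paclitaxel (SD, n = 3), CEP295NL, NEB, ATG9B and IGFN1 (log2 6.52 to 7.42 for these 4). The largest falls were UGT1A10, which had 0 counts under paclitaxel, HIST1H4I, HIST1H4L, HIST1H4C and CDH10 (-4.31 to -3.73 for these 4). The edgeR test called 12007 of 19151 genes, 6169 higher and 5838 lower, 8114 of them at least 2-fold. Camera called 9 lists and 0 with an estimated correlation (fry called 13); adjusted over the list alone, the counts were 20 lower for G1/S, 18 higher for NF-kB and 2 higher with 14 lower for NRF2 targets, and as given for the others.

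A/S in PC9 asked what blocking the anti-apoptotic BCL-2 family proteins did to transcription in the cells left to sequence. Stress response and inflammatory genes rose and cholesterol synthesis genes fell. Of 44 stress response and ATF4 targets 19 rose and 0 fell (25 higher adjusted over the list alone; camera adjusted p = 1.12e-26, and adjusted p = 0.0407 with an estimated correlation). CHAC1, which degrades glutathione, went from 2.36 ± 0.271 to 25.1 ± 3.00 CPM (SD, n = 3 each; log2 change 3.41 ± 0.20 SE, edgeR adjusted p = 7.1e-06), and STC2, SESN2, ASNS and DDIT3 changed by 2.42 ± 0.13, 2.47 ± 0.22, 1.73 ± 0.31 and 1.66 ± 0.19. ATF4 mRNA was 623 ± 79.6 against 378 ± 15.8 CPM and was not called (0.72 ± 0.27, edgeR adjusted p = 0.14). Of 20 NF-kB and inflammatory genes 14 rose (18 adjusted over the list alone), such as RELB (2.85 ± 0.26), IL6 (3.25 ± 0.38) and TNFAIP3 (2.96 ± 0.37), with adjusted p = 0.0627 with an estimated correlation. Of 21 cholesterol synthesis genes 19 fell (20 adjusted over the list alone), such as HMGCS1 (-2.17 ± 0.19), MVK (-2.23 ± 0.21) and LSS (-1.99 ± 0.22), and the list kept its call with an estimated correlation (adjusted p = 0.036). So did the YAP/TEAD targets (camera adjusted p = 0.036), of which 5 of 16 rose and 7 adjusted over the list alone, such as DLC1 (1.10 ± 0.17).

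Of the other lists called for PC9 A/S, among anti-apoptotic genes BCL2L1 (0.66 ± 0.16) and BCL2L2 (0.58 ± 0.14) rose, 2 of 4 measured and 3 adjusted over the list alone (adjusted p = 0.342 with an estimated correlation), and MCL1 was not called at 0.47 ± 0.15. FOSL1 (2.30) was among 3 of 19 ERK output genes that rose, 6 with 1 lower adjusted over the list alone (adjusted p = 0.692 with an estimated correlation), and HERPUD1 (1.26) and HSPA5 (0.83) were the 2 of 18 ER chaperone genes that rose, 3 adjusted over the list alone (adjusted p = 0.96 with an estimated correlation). The nuclear OXPHOS list was lower as a whole with 0 of 29 genes called by edgeR, over all genes or adjusted over the list alone (adjusted p = 0.96 with an estimated correlation). CDKN1A rose by 2.08 ± 0.43. The largest rises were CXCL8, SGPP2, IGFN1, TRAF1 and SERPINB2 (3.52 to 5.07) and among the largest falls were STARD4, INSIG1, SCD and MAP2K6 (-2.98 to -2.74), of which the first 3 belong to sterol and fatty acid metabolism. The edgeR test called 1193 of 19151 genes, 604 higher and 589 lower, 604 of them at least 2-fold. In a fit of the 2 groups alone the count was 4098, and by DESeq2 2259. The 1193 rested on every library: without A/S library 1, 2 or 3 it was 764, 408 and 771, and without DMSO library 1, 2 or 3 it was 464, 411 and 464. Without any 1 of these except A/S library 3, BCL2L1, BCL2L2, HSPA5 and CDKN1A lost their calls (edgeR adjusted p = 0.0551 to 0.191), as did IGFN1 without DMSO library 1, 2 or 3 (0.0512 to 0.0536). Camera lost the ER chaperone and anti-apoptotic lists without A/S library 1 (adjusted p = 0.642 and 0.119), and the OXPHOS list without A/S library 3 (0.179).

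Set directly against A/S, erlotinib had lower proliferation and ERK output genes. All 24 G1/S genes, all 26 G2/M genes (MKI67 -2.58) and all 11 histone genes were lower, as were 17 of 19 ERK output genes with 1 higher (DUSP6 -3.89) and 3 of 4 anti-apoptotic genes, BCL2L1 (-1.11) and MCL1 (-0.80) among them; each of these lists had adjusted p = 0.321 with an estimated correlation. NF-kB genes (3 higher and 13 lower of 20) and ER chaperones (8 lower of 18) had adjusted p = 0.774, NRF2 targets (2 and 9 of 18) adjusted p = 0.573, and ribosomal proteins, with 0 of 33 called by edgeR, adjusted p = 0.823 with an estimated correlation. NF-kB genes had 4 higher and 14 lower and NRF2 targets 11 lower adjusted over the list alone, and the others kept their counts. IGFBP5, TP53INP1, VTCN1, FCGBP and NUPR1 were the largest differences upward (5.43 to 6.85), and PTHLH, FST, HMGA2, DUSP6 and SERPINB2 downward (-4.50 to -3.86). In all, 7703 of 19151 genes differed, 4205 higher and 3498 lower under erlotinib; without erlotinib library 3 the count was 11749, and in a fit of the 2 groups 4133. Camera called 9 lists and 0 with an estimated correlation (fry 13). The ribosomal list lost its call without erlotinib library 1 or 2 (adjusted p = 0.142 and 0.0599).

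Paclitaxel set against A/S had lower cell cycle genes and also lower ATF4 targets. Of 44 ATF4 targets 28 were lower and 7 higher, CHAC1 at -1.57 ± 0.18 and ATF3 at 1.49 ± 0.17 (29 lower adjusted over the list alone; adjusted p = 0.547 with an estimated correlation). All 26 G2/M genes (MKI67 -1.49) and 20 of 24 G1/S genes were lower (adjusted p = 0.527 with an estimated correlation), and so were all 11 histone genes, 14 of 18 NRF2 targets with 1 higher, and 10 of 16 YAP/TEAD targets with 3 higher (adjusted p = 0.453). ER chaperones (1 higher and 14 lower of 18), mitochondrial chaperones (1 and 10 of 15), OXPHOS genes (23 lower of 29) and ribosomal proteins (30 lower of 33) had adjusted p = 0.583 with an estimated correlation; adjusted over the list alone their lower counts were 15, 10, 25 and 32. Of 13 mitochondrially encoded mRNAs 8 were higher, such as MT-ND1 (2.53 ± 0.70), and of 8 fibroblast, endothelial and leukocyte markers 6, such as VWF (3.44 ± 0.47), with adjusted p = 0.638 and adjusted p = 0.453 with an estimated correlation. Among the largest differences were, upward, AC006064.6, which had 0 counts under A/S, ATG9B, NEB and FAM83E, and downward AL035078.4, which had 0 counts under paclitaxel, AC034102.3, HIST1H4L, HIST1H4I and HIST1H2BL. In all, 10481 of 19151 genes differed, 5206 higher and 5275 lower under paclitaxel; camera called 12 lists, 0 with an estimated correlation, and fry 19. AL035078.4 lost its edgeR call without any 1 paclitaxel library or A/S library 1 (adjusted p = 0.0529 to 0.0607). Camera lost the mitochondrial mRNAs without paclitaxel or A/S library 1 or 2 (adjusted p = 0.0531 to 0.0821) and the YAP/TEAD list without paclitaxel library 3 (0.0526).

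Erlotinib and paclitaxel shared 6292 genes called in the same direction, against 2622 expected if the calls were independent, with 186 called in opposite directions. A/S shared 715 genes with paclitaxel (374 expected, 101 opposite) and 406 with erlotinib (260 expected, 219 opposite). The groups share 3 DMSO libraries, and simulated data with that sharing and no change gave at most 1 shared gene in 20 draws; 3 controls cannot be split into separate parts of at least 2, so part of the excess may come from the shared control. Pearson's r across genes was 0.797 for erlotinib with paclitaxel, 0.482 for A/S with paclitaxel and 0.340 for A/S with erlotinib, where sharing alone gave 0.461 to 0.484, and the covariances were 1.82, 0.682 and 0.369 where sharing alone gave 0.0706 to 0.0716.

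**Figure D3:**
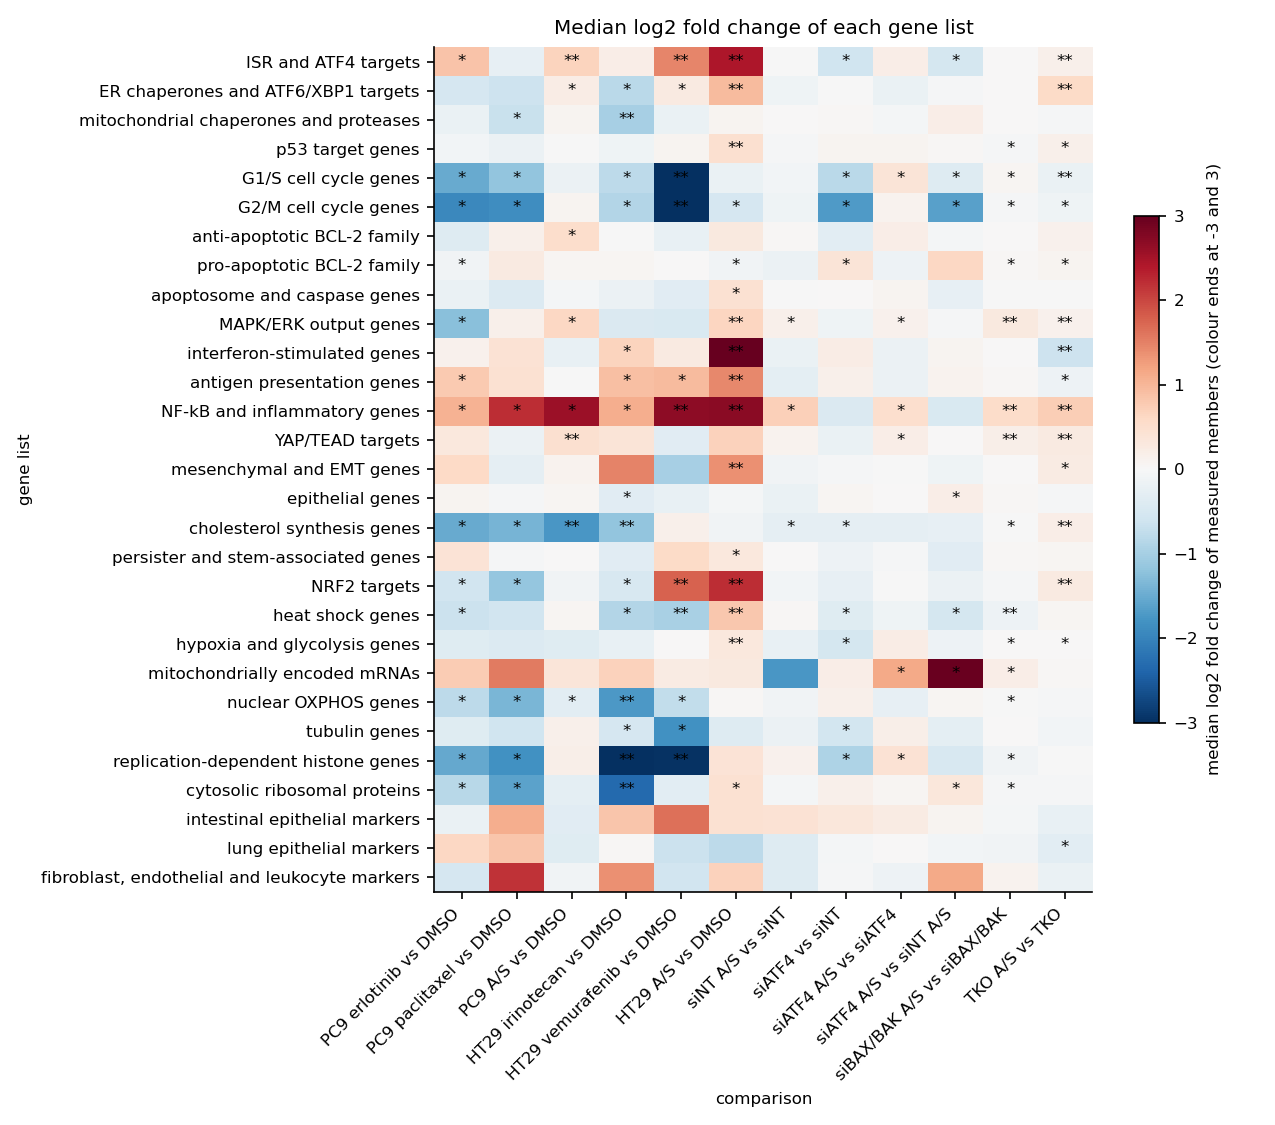
Median log2 change of each fixed gene list (rows) in each comparison (columns), colour from lower to higher. One star marks lists called by camera and 2 stars those called also with an estimated correlation; cholesterol synthesis genes carry 2 stars in PC9 A/S, and ATF4 targets carry 2 in both lines under A/S.

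HT29 cells under irinotecan, a topoisomerase I inhibitor, had lower growth machinery and higher immune genes than with DMSO. All 33 cytosolic ribosomal proteins, such as RPS23 (-2.84 ± 0.05) and RPL5 (-2.61 ± 0.05), all 29 nuclear OXPHOS genes, such as COX7A2 (-3.76 ± 0.07), and all 12 histone genes, such as HIST1H3B (-4.44 ± 0.06), fell. Of 21 cholesterol synthesis genes 19 fell, such as SQLE (-1.89) and FDPS (-1.86), with 1 higher, and of 15 mitochondrial chaperones 14, such as HSPE1 (-2.34), with 1 higher. These 5 lists kept their calls with an estimated correlation (adjusted p = 0.0147 to 0.0481). On average lncRNA took 5.11% of counts against 1.66% in DMSO and ERCC spike-ins 2.96% against 0.214%, and 24953 genes were detected against 21672. Antigen presentation genes rose in 11 of 12 cases, such as HLA-B (3.61 ± 0.08) and NLRC5 (4.24 ± 0.11), interferon-stimulated genes in 18 of 23 with 2 lower, such as MX1 (1.85), and NF-kB genes in 12 of 19 with 4 lower, such as ICAM1 (2.77), with adjusted p = 0.0818, 0.0886 and 0.0886 with an estimated correlation. Of 26 G2/M genes 25 fell, such as CCNB1 (-1.66), and of 24 G1/S genes 20, such as PCNA (-1.96), with 2 higher (adjusted p = 0.0886 and adjusted p = 0.0818 with an estimated correlation), while MKI67 was not called at 0.10 ± 0.05. ATF4 fell by 1.06 while DDIT3 (2.83 ± 0.08) and CHAC1 (2.81 ± 0.11) rose; of 43 ATF4 targets 22 rose and 17 fell, and the list was not called.

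Of the other lists called under irinotecan, ER chaperones (1 higher and 13 lower of 18), epithelial genes (5 and 13 of 19), NRF2 targets (3 and 12 of 18), heat shock genes (2 and 8 of 11) and tubulins (4 and 7 of 11) were lower, with adjusted p = 0.116, 0.131, 0.228, 0.124 and 0.357 with an estimated correlation. Counts adjusted over the list alone equalled those given. CDKN1A rose (1.87 ± 0.07) and MCL1 fell by 0.71. The largest rises were UPK2, CEP295NL, APOE, GPNMB and FLNC (5.62 to 9.08) and the largest falls 5 histone genes, HIST1H2BB, HIST1H4L, HIST1H4B, HIST1H4C and HIST1H3J (-5.11 to -4.88). In all edgeR called 14528 of 17978 genes, 7505 higher and 7023 lower, 8086 at least 2-fold. Camera called 15 lists, 5 with an estimated correlation, and fry 28.

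Vemurafenib inhibits mutant BRAF, the HT29 driver, and cells under it had lower division genes. All 26 G2/M genes fell, and MKI67 went from 1315 ± 32.6 to 43.5 ± 2.45 CPM (SD, n = 3 each; -4.92 ± 0.06). All 24 G1/S genes, such as RRM2 (-4.68 ± 0.06), all 12 histone genes and 10 of 11 heat shock genes, such as HSPA8 (-1.67), fell. ATF4 rose by 1.04 ± 0.04 and 38 of 43 ATF4 targets rose with 2 lower, such as DDIT4 (3.85), ASNS (2.45) and TRIB3 (2.95). NRF2 targets rose in 17 of 18 cases, with the aldo-keto reductases AKR1C1 and AKR1B10 at 7.41 ± 0.07 and 4.85 ± 0.07, and NF-kB genes in 15 of 19 with 3 lower, such as ICAM1 (3.85). These 7 lists kept their calls with an estimated correlation (adjusted p = 5.13e-05 to 0.012). Antigen presentation genes (10 higher and 1 lower of 12), ER chaperones (9 and 7 of 18), OXPHOS genes (1 and 28 of 29) and tubulins (9 lower of 11) were called with adjusted p = 0.245, 0.261, 0.263 and 0.0503 with an estimated correlation. ERK output genes went both ways, 6 higher and 12 lower of 19, with DUSP6 at -1.86 ± 0.06 and DUSP5 at 3.15 ± 0.06, and the list was not called. ATF4 targets had 39 higher adjusted over the list alone, and the other lists kept their counts.

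The largest rises under vemurafenib were UBD, which had 0 counts in all 3 DMSO libraries and 32.4 ± 1.40 CPM under the drug (SD, n = 3), PLA2G4C, AKR1C1, NEURL3 and AKR1C2 (7.04 to 7.75 for these 4), and the largest falls KIF20A, TNS4, HIST1H3D, AKAP12 and S100A2 (-6.27 to -5.76). BBC3 (2.47), BMF (2.37) and PMAIP1 (1.37), which encode BH3-only proteins, rose, and BCL2L1 fell by 0.50. In all edgeR called 13097 of 17978 genes, 6655 higher and 6442 lower, 5833 at least 2-fold; lncRNA took 4.17% of counts on average against 1.66% in DMSO. Camera called 11 lists, 7 with an estimated correlation, and fry 27.

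A/S in HT29 was followed by higher stress response, interferon and inflammatory genes. Of 43 ATF4 targets 42 rose, and ATF4 itself went from 258 ± 1.04 to 953 ± 11.8 CPM (SD, n = 3 each; 1.88 ± 0.04), with ATF3 at 4.62 ± 0.07, CHAC1 at 5.46 ± 0.10 and ASNS at 3.98 ± 0.05 (camera adjusted p = 7.1e-05 with an estimated correlation). Of 23 interferon-stimulated genes 22 rose, such as RSAD2 (7.59 ± 0.06) and IFIT2 (7.67 ± 0.07), and the interferon genes IFNL1 (9.01 ± 0.17) and IFNB1 (7.85 ± 0.23) were among the 5 largest rises, with SLFN11, KRT17 and SCN3A. NF-kB genes rose in 18 of 19 cases with 1 lower (TNFAIP3 5.32), antigen presentation genes in 11 of 12 (TAP1 3.17), all 18 NRF2 targets (TXNRD1 2.68) and all 18 ER chaperones (HERPUD1 2.85, XBP1 2.54). ERK output (15 higher and 4 lower of 19; DUSP5 3.62), heat shock (9 and 2 of 11), hypoxia and glycolysis (10 and 3 of 16; NDRG1 4.36), mesenchymal (6 and 1 of 8) and p53 target genes (12 and 9 of 23; CDKN1A 5.28 ± 0.07) were also higher. These 11 lists kept their calls with an estimated correlation (adjusted p = 1.39e-05 to 0.0451).

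Under the same treatment MCL1, whose protein S63845 binds, rose by 2.27 ± 0.05, from 354 ± 5.95 to 1709 ± 81.2 CPM (SD, n = 3 each), and the BH3-only genes PMAIP1 and BBC3 by 5.53 ± 0.08 and 3.42 ± 0.08. Pro-apoptotic genes went both ways, 4 higher and 5 lower of 10 with a median of -0.10 and a mean of 0.90, as did apoptosome and caspase genes (9 and 6 of 16) and persister and stem-associated genes (9 and 5 of 16; KLF4 6.21, LGR5 -3.60); with an estimated correlation they had adjusted p = 0.163, 0.267 and 0.127. All 33 ribosomal proteins were higher (median 0.47; adjusted p = 0.441 with an estimated correlation) and 23 of 26 G2/M genes lower with 1 higher (MKI67 -0.39 ± 0.05; adjusted p = 0.105). Cholesterol synthesis genes, 8 higher and 10 lower of 21, were not called as a list. Adjusted over the list alone, 1 ATF4 target was lower, caspase genes had 10 higher and cholesterol genes 12 lower. The largest falls were KCNE3, ZNF792, SOSTDC1, SLITRK6 and LGR5 (-4.46 to -3.60). The edgeR test called 11964 of 17978 genes, 5955 higher and 6009 lower, 4401 at least 2-fold; camera called 16 lists, 11 with an estimated correlation, and fry 26.

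Irinotecan set against A/S in HT29 had lower stress response, interferon and growth genes. ATF4 targets (3 higher and 38 lower of 43; ASNS -3.90, ATF4 -2.95), interferon-stimulated genes (1 and 22 of 23; RSAD2 -6.21), NRF2 targets (17 lower of 18), ribosomal proteins (33 lower of 33), OXPHOS genes (29 lower of 29), histone genes (12 lower of 12) and ER chaperones (1 and 17 of 18) were lower, as were NF-kB, heat shock, hypoxia, mitochondrial chaperone, ERK output and cholesterol synthesis genes (17, 10, 13, 14, 14 and 17 lower). These 13 lists kept their calls with an estimated correlation (adjusted p = 0.000475 to 0.0494). The p53 targets (6 and 14 of 23), G1/S genes (4 and 19 of 24) and tubulins (1 and 8 of 11) had adjusted p = 0.0794, 0.265 and 0.257 with an estimated correlation. MCL1 was lower by -2.99 and CDKN1A by -3.41. UPK2, FAM131B, ADGRB2, SALL4 and GPNMB were the largest differences upward (5.86 to 8.80), and SLFN11, IFNL1, CXCL11, CCL5 and CXCL10 downward (-9.56 to -7.26). In all 14821 of 17978 genes differed, 7474 higher and 7347 lower under irinotecan; camera called 16 lists and fry 26, and counts adjusted over the list alone equalled those given. The G1/S list lost its call without irinotecan library 1 or 3 (camera adjusted p = 0.0552 and 0.0584).

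Vemurafenib set against A/S had lower division genes, with all 24 G1/S and all 26 G2/M genes lower (MKI67 -4.53), all 19 ERK output genes lower (PHLDA1 -2.66, DUSP6 -2.21) and 22 of 23 interferon-stimulated genes lower with 1 higher. Heat shock genes (11 of 11), histone genes (12 of 12), tubulins (10 of 11), mesenchymal genes (5 of 8 with 1 higher) and ATF4 targets (36 of 43 with 4 higher; ATF4 -0.84) were also lower, and these 9 lists kept their calls with an estimated correlation (adjusted p = 0.000183 to 0.0399). NRF2 targets were higher, 11 with 6 lower of 18 (AKR1C1 3.20; adjusted p = 0.127 with an estimated correlation). Ribosomal proteins (33 lower), OXPHOS genes (1 higher and 28 lower), ER chaperones (16 lower), p53 targets (7 and 15 of 23) and hypoxia genes (4 and 9 of 16) had adjusted p = 0.368, 0.379, 0.1, 0.127 and 0.1 with an estimated correlation. UBD, TRPM6, IL34, KCNE3 and SLC38A4 were the largest differences upward (5.65 to 7.57), and IFNL1, SLFN11, CXCL11, CXCL10 and SCN3A downward (-11.20 to -8.91). In all 13825 of 17978 genes differed, 6737 higher and 7088 lower under vemurafenib; camera called 15 lists and fry 27, and adjusted over the list alone 37 ATF4 targets were lower, with the other counts as given.

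In HT29, irinotecan and vemurafenib shared 8751 genes called in the same direction (5295 expected), A/S and vemurafenib 5718 (4358 expected) and A/S and irinotecan 5695 (4833 expected), with 2330, 3577 and 4318 called in opposite directions. Pearson's r across genes was 0.53, 0.282 and 0.241, where sharing the DMSO libraries alone gave 0.436, 0.485 and 0.454 in simulated data, and the covariances were 1.27, 0.564 and 0.527 where sharing alone gave 0.0205. The limit given for the shared PC9 controls applies here too. A/S in PC9 and A/S in HT29, which share no library, had 778 genes called in the same direction (434 higher, 344 lower, 366 expected) and 138 in opposite directions, with r of 0.303 across genes.

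The difference between the A/S effects of the lines was tested directly. ATF4 targets rose more in HT29, 40 higher and 1 lower of 44, with DDIT4 (4.53), WARS (3.92), ATF3 (3.65) and ATF4 (1.12 ± 0.12) among them. Interferon-stimulated genes (20 of 23), NRF2 targets (18 of 18), hypoxia genes (9 with 2 lower of 17), heat shock genes (8 of 11) and persister and stem-associated genes (9 with 3 lower of 17; KLF4 5.07) also had the higher effect in HT29, and these 6 lists kept their calls with an estimated correlation (adjusted p = 4.69e-05 to 0.0406). Cholesterol synthesis genes (19 of 21), ribosomal proteins (32 of 33), antigen presentation genes (9 of 12), ER chaperones (11 of 18), p53 targets (13 with 4 lower of 23) and pro-apoptotic genes (3 with 2 lower of 11; PMAIP1 4.78) were higher and G2/M genes lower (20 of 26), with adjusted p = 0.298, 0.492, 0.229, 0.545, 0.492, 0.298 and 0.359 with an estimated correlation. ER chaperones had 12 higher, hypoxia genes 11 higher and G2/M genes 22 lower adjusted over the list alone. MCL1 (1.76) and CDKN1A (3.16) had higher effects in HT29, and DUSP6 (-0.41) and MKI67 (-1.09) lower ones. In all 7051 of 17978 genes differed, 3436 higher and 3615 lower, 3009 at least 2-fold; camera called 13 lists and fry 21.

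**Figure D4:**
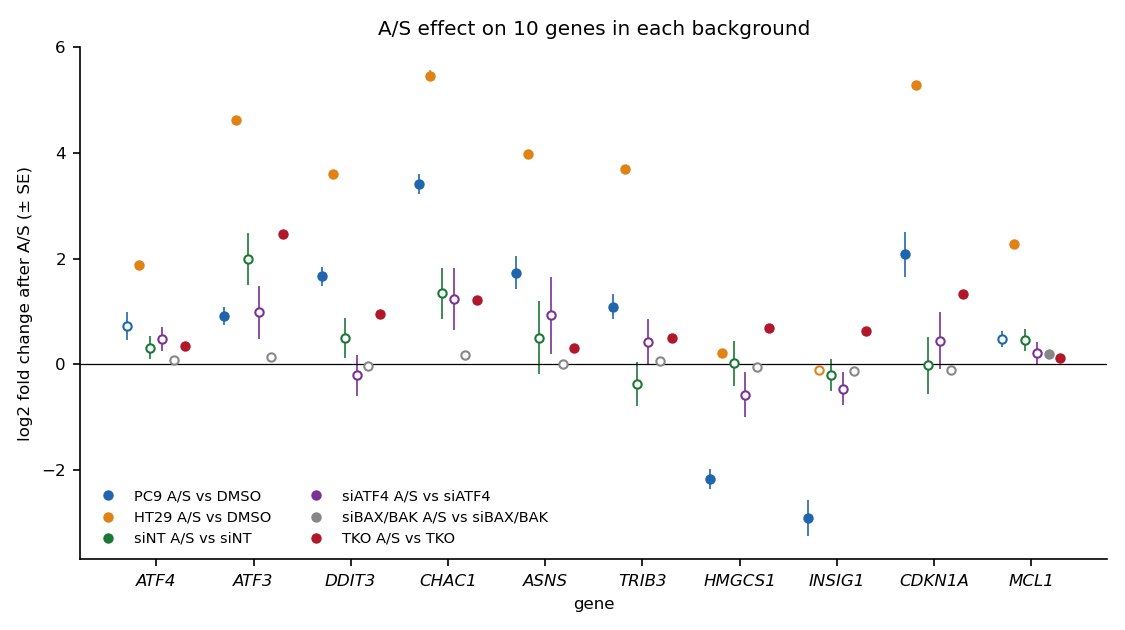
Log2 change after A/S with its SE for 10 genes in 6 backgrounds; filled points passed the edgeR test and open points did not. CHAC1 stands at 3.41 in PC9 and 5.46 in HT29.

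The siNT and siATF4 libraries asked whether the response to A/S needs ATF4. In siNT cells A/S gave no called gene: edgeR called 0 of 18089, with 220 at an unadjusted p under 0.05, and DESeq2 called 4. NF-kB genes were higher as a list, with CXCL8 at 2.23 ± 0.62, ERK output genes higher, with EGR1 at 2.23, and cholesterol synthesis genes lower, with MVK at -0.81, each with 0 members called over all genes and 2, 1 and 0 adjusted over the list alone. With an estimated correlation the 3 lists had adjusted p = 0.0764, 0.0764 and 0.581, and fry called 0. ATF3, CHAC1 and ATF4 stood at 1.99, 1.34 and 0.32, not called. The siBAX/BAK-like profile moved as well, with shares of 4.59%, 0.96% and 4.44% in siNT libraries 1 to 3 and 2.07%, 11.59% and 12.89% with A/S. Without siNT A/S library 1 camera called 9 lists, without siNT library 2 it called 6, and without siNT library 1, siNT library 3 or siNT A/S library 3 it called 5; with the 4 libraries rich in mitochondrial mRNA left out edgeR called 609 genes. The ERK output list was lost without siNT library 1 (camera adjusted p = 0.0648), and the cholesterol list without siNT library 2 or siNT A/S library 2 (0.0571 and 0.13).

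siATF4 against siNT lowered ATF4 by a log2 change of -1.88 ± 0.23 (adjusted p = 0.01) and 10 other genes. Among them were PSAT1, which makes serine and is an ATF4 target (-2.81 ± 0.44), ABCA13 (-4.23), YWHAH (-2.37), ZBED2 (-2.30) and SMARCD1 (-2.29). Of 44 ATF4 targets 2 fell, and 12 fell with 2 higher adjusted over the list alone; ASNS at -3.13, CHAC1 at -3.53 and DDIT3 at 2.00 were not called over all genes. G2/M genes were lower as a list with 0 of 26 called by edgeR and 23 adjusted over the list alone (KIF20A -2.71, MKI67 -1.68), and G1/S genes with 0 of 24 and 8 (CDC6 -1.52). These 3 lists had adjusted p = 0.0867 with an estimated correlation and 0.0197 by fry. Histone, tubulin, hypoxia, heat shock and cholesterol genes were lower and pro-apoptotic genes higher as lists, with 0 members called (0, 2, 2, 0, 0 and 1 adjusted over the list alone) and adjusted p = 0.225, 0.347, 0.257, 0.511, 0.682 and 0.391 with an estimated correlation. The count was 11 of 18089, and DESeq2 called 528. It was 0 in a fit of the 2 groups and without siATF4 library 1 or 3, where the ATF4 change of -1.89 or -1.85 was not called, 5 without siNT library 1 or 3, 46 without siATF4 library 2 and 145 without siNT library 2; with the mitochondrial mRNA-rich libraries left out it was 4724. PSAT1, ABCA13 and ZBED2 lost their calls without siNT library 1 or 3 (edgeR adjusted p = 0.151 to 0.188). Without siATF4 library 2 the pro-apoptotic and heat shock lists had camera adjusted p = 0.328 and 0.103, and without siNT library 2 the cholesterol list 0.246.

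In siATF4 cells A/S also gave 0 called genes of 18089 by edgeR (404 at an unadjusted p under 0.05; DESeq2 called 1), with ATF4 at 0.47 ± 0.23 and CHAC1 not called. Profile shares were 5.97%, 0.55% and 5.67% in siATF4 libraries 1 to 3 and 0% (upper quartile 4.81%), 2.7% and 13.93% with A/S. Camera called 6 lists higher, G1/S, NF-kB, histone, YAP/TEAD, ERK output and mitochondrially encoded mRNAs, each with 0 members called over all genes (YAP/TEAD 2 and ERK output 1 adjusted over the list alone, the others 0). Their adjusted p with an estimated correlation was 0.408 for G1/S, NF-kB, YAP/TEAD and ERK output, adjusted p = 0.437 for histones and adjusted p = 0.843 for the mitochondrial mRNAs. The last list was lower without siATF4 library 2 and A/S libraries 1 and 2, but these were chosen on its level and 1 A/S library remains. Without siATF4 A/S library 2 camera called 2 lists, G1/S and NF-kB, the only ones that kept their calls whichever library was left out, and ERK output, YAP/TEAD, the mitochondrial mRNAs and histones had adjusted p = 0.172, 0.172, 0.31 and 0.0991.

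With A/S in both arms, siATF4 lowered ATF4 by -1.73 ± 0.23, EIF4EBP2 by -2.14 and SMARCD1 by -1.81 (edgeR adjusted p = 0.043 for each), the 3 genes called of 18089. DESeq2 called 936. Of 44 ATF4 targets 1 fell, ATF4 itself, and 4 higher and 14 lower passed adjusted over the list alone; ASNS at -2.71 and CHAC1 at -3.64 were not called over all genes. G2/M genes were lower with 0 called and 22 adjusted over the list alone. These lists had adjusted p = 0.505 with an estimated correlation. Mitochondrially encoded mRNAs (median 2.97), epithelial genes and ribosomal proteins were higher and G1/S and heat shock genes lower with 0 members called (0, 4 with 1 lower, 0, 1 and 1 adjusted over the list alone; adjusted p = 0.953 with an estimated correlation), where 2 of the 3 siATF4 A/S libraries are rich in mitochondrial mRNA. Leaving out any 1 of the 6 libraries gave 0 genes, the ATF4 change then lying between -1.88 without siATF4 A/S library 1 and -1.65 without siATF4 A/S library 3; with the block or in a fit of the 2 groups it was 0 too. Without libraries rich in mitochondrial mRNA 1 siATF4 A/S library is left, with a profile share of 13.93%, so that fit decides nothing. Without siATF4 A/S library 3 camera called 4 lists in place of 7. ATF4 targets and G2/M kept their calls whichever library was left out; without that library G1/S, epithelial and ribosomal genes had adjusted p = 0.634, 0.214 and 0.515, and without siATF4 A/S library 1 heat shock genes and mitochondrial mRNAs 0.0684.

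The difference between the A/S effects under siATF4 and siNT was called for 0 of 18089 genes by edgeR, with 218 at an unadjusted p under 0.05 and 1 called by DESeq2. ATF4 stood at 0.16 ± 0.32. Camera called 5 lists, G1/S genes, mitochondrially encoded mRNAs (median 2.83), hypoxia genes, tubulins and histone genes, with 0 members called over all genes or adjusted over the list alone and adjusted p = 0.847 with an estimated correlation. Without siATF4 A/S library 2 it called 1 list, and without siNT library 1 or 3, siNT A/S library 2 or siATF4 A/S library 3 it called 3. Only G1/S kept its call whichever library was left out. The mitochondrial mRNAs had adjusted p = 0.693 without siNT library 2. Leaving out the libraries rich in them selects on that list and leaves 1 siATF4 A/S library. The data do not show that the A/S response differed with ATF4 lowered, nor that it did not.

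The libraries labelled siBAX/BAK were meant to show A/S with BAX and BAK lowered, which cells so unlike other PC9 groups do not establish. NF-kB, YAP/TEAD and ERK output genes rose after A/S and heat shock genes fell. Of 16 YAP/TEAD targets 9 rose, such as CCN1 (1.32 ± 0.04), CCN2 (1.77) and AMOTL2 (0.83). Of 18 NF-kB genes 6 rose (8 adjusted over the list alone), such as NFKBIA (0.54), PTGS2 (0.93) and ICAM1 (1.45), of 19 ERK output genes 9 rose and 2 fell (12 and 2 adjusted over the list alone; ETV5 1.04, DUSP6 0.58), and of 11 heat shock genes 5 fell (8 adjusted over the list alone; HSPA1B -1.06, HSPA1A -0.96). These 4 lists kept their calls with an estimated correlation (adjusted p = 5.51e-05 to 0.0045). ATF4 was not called at 0.08 and MCL1 rose by 0.19. The other 10 called lists had at most 5 members called (6 adjusted over the list alone) and medians between -0.12 and 0.20, with adjusted p = 0.137 to 0.636 with an estimated correlation. The largest rises were CCN1, ID1, THBS1, SMAD7 and SKIL (1.02 to 1.32) and the largest falls HSPA1B, HSPA1A, SLITRK3, PHLDA3 and SIM1 (-1.06 to -0.43). In all edgeR called 762 of 20383 genes, 41 at least 2-fold. Of these 585 were higher and 177 lower, or 562 and 495 by DESeq2. DUSP6 lost its call without siBAX/BAK library 1, 3 or 4 or A/S library 1, 2 or 4 (edgeR adjusted p = 0.0717 to 0.119), and the 4 lists named kept theirs.

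In the libraries labelled triple knockout A/S was followed by higher ER stress, ATF4 and inflammatory genes. Of 18 ER chaperone and ATF6/XBP1 genes 17 rose, such as HERPUD1 (2.18), DNAJB9 (1.87) and XBP1 (1.06). Of 44 ATF4 targets 25 rose and 1 fell, with ATF3 at 2.46, PPP1R15A at 1.09 and ATF4 at 0.35 ± 0.03, and of 18 NF-kB genes 15 rose and 1 fell (PTGS2 1.92, IL11 1.78). NRF2 targets (12 of 18; TXNRD1 0.66), YAP/TEAD targets (10 with 1 lower of 16; CCN2 1.21), ERK output genes (10 with 1 lower of 19) and cholesterol synthesis genes (14 with 3 lower of 21; HMGCS1 0.70, INSIG1 0.64) also rose, while interferon-stimulated genes (15 of 22; IFI6 -0.90) and G1/S genes (19 of 24; TYMS -0.41) fell. These 9 lists kept their calls with an estimated correlation (adjusted p = 4.72e-07 to 0.038). G2/M (1 and 15 of 26), p53 (13 and 4 of 24), mesenchymal (10 and 2 of 21), pro-apoptotic (5 and 2 of 11), hypoxia (6 and 2 of 17), antigen presentation (1 and 6 of 12) and lung epithelial genes (2 lower of 7) had adjusted p = 0.23, 0.0724, 0.0724, 0.166, 0.151, 0.354 and 0.151 with an estimated correlation. The antigen presentation list was lost without knockout library 1, 2 or 4 or knockout A/S library 1 or 4 (adjusted p = 0.0538 to 0.0686).

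In the knockout the counts adjusted over the list alone were 26 higher and 2 lower for ATF4 targets, 18 higher for ER genes, 11 higher for YAP/TEAD targets, 22 lower for G1/S, 17 lower for G2/M and 16 lower for interferon-stimulated genes, with the others at most 2 genes away from those given. CDKN1A rose by 1.32, CHAC1 by 1.21 and DDIT3 by 0.95. The largest rises were FOSB, CYP1B1, ATF3, IL6 and HERPUD1 (2.18 to 2.99) and the largest falls SPRY1, DGAT2, ABCA1, MAP2K6 and CHST6 (-1.55 to -1.14). The edgeR test called 6285 of 20383 genes, 3108 higher and 3177 lower, 294 of them at least 2-fold; camera called 16 lists, 9 with an estimated correlation, and fry 22.

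The A/S effects of the knockout and of the libraries labelled siBAX/BAK differed in 2814 of 20383 genes, 1325 higher and 1489 lower in the knockout, or 1827 and 1159 with DESeq2 size factors. ER chaperones (17 of 18; HERPUD1 2.24, DNAJB9 1.77), ATF4 targets (19 with 1 lower of 44; ATF3 2.32, CHAC1 1.04, ATF4 0.27), p53 targets (10 of 24; CDKN1A 1.43), NRF2 targets (12 of 18), cholesterol synthesis genes (12 of 21) and NF-kB genes (5 with 2 lower of 18) had the higher effect in the knockout. G1/S genes (18 of 24) and interferon-stimulated genes (7 of 22) had the lower effect. These 8 lists kept their calls with an estimated correlation (adjusted p = 8.11e-06 to 0.0443). Heat shock genes (7 higher of 11), G2/M (1 and 5 of 26), antigen presentation (4 lower of 12) and mesenchymal genes (3 higher of 21) had adjusted p = 0.0554, 0.606, 0.386 and 0.333 with an estimated correlation. Adjusted over the list alone, ATF4 targets had 20 higher, G1/S genes 21 lower and the others at most 2 genes more. The largest differences upward were CYP1B1, ATF3, HERPUD1, DNAJB9 and CXCR4 (1.74 to 2.62), and downward MATK, which had 0 counts in the knockout with A/S, ID1, SERPINB2, ABCA1 and CBLC. CBLC lost its edgeR call without siBAX/BAK library 1 or 3 or A/S library 2 (adjusted p = 0.0546 to 0.141), and MATK without siBAX/BAK A/S library 1, knockout library 3 or 4 or any knockout A/S library (0.0508 to 0.119). Camera lost G2/M without any 1 of 11 of the 16 libraries, such as knockout library 4 (0.119), NF-kB without siBAX/BAK A/S library 3 (0.0756), and antigen presentation and mesenchymal genes without knockout A/S library 4 (0.0539).

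Against unedited PC9, the knockout had a different A/S effect in cholesterol synthesis and ATF4 target genes. All 21 cholesterol synthesis genes were higher in the difference, such as HMGCS1 (2.86), STARD4 (3.74) and MSMO1 (2.74); 19 of them had fallen in PC9. Of 44 ATF4 targets 28 were lower and 5 higher, with CHAC1 at -2.21, STC2 at -1.52, ASNS at -1.42 and ATF3 at 1.54, and of 19 ERK output genes 13 were lower and 2 higher (SPRY4 -1.59). These 3 lists kept their calls with an estimated correlation (adjusted p = 0.0249, 0.0447 and 0.00594). NF-kB genes (15 lower of 19; TNFAIP3 -2.23), hypoxia genes (11 higher and 2 lower of 17), NRF2 targets (9 and 1 of 18), OXPHOS genes (9 higher of 29), ribosomal proteins (4 higher of 33), ER chaperones (5 higher of 18) and G2/M genes (8 lower of 26) had adjusted p = 0.255, 0.0584, 0.0701, 0.767, 0.767, 0.767 and 0.767 with an estimated correlation. Adjusted over the list alone, 30 ATF4 targets, 17 NF-kB genes and 9 G2/M genes were lower, and 13 OXPHOS genes, 11 NRF2 targets with 2 lower, 7 ER chaperones with 1 lower and 0 ribosomal proteins higher. In all 5328 of 19289 genes differed, 2775 higher and 2553 lower, or 2380 and 2845 with DESeq2 size factors, 1066 at least 2-fold. Camera lost G2/M and NRF2 without PC9 A/S library 1 (adjusted p = 0.204 and 0.0556) and ER and ribosomal genes without PC9 A/S library 3 (0.155 and 0.221). The groups also differ in library kind, so this difference mixes the knockout with the kind of library.

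The A/S effect in the libraries labelled siBAX/BAK minus that in siNT was called for 3 of 21163 genes. PLAU was higher (1.22 ± 0.15), but at 4.70 CPM with A/S against 588 in siNT with A/S. TXNIP and ARRDC4, which encode arrestin-like limiters of glucose uptake, were lower (-1.22 ± 0.15 and -1.39 ± 0.18). Heat shock genes were lower and YAP/TEAD, cholesterol, hypoxia and antigen presentation genes higher as lists, with 0 members called over all genes (3, 1, 0, 0 and 0 adjusted over the list alone) and adjusted p = 0.248, 0.544, 0.816, 0.615 and 0.615 with an estimated correlation. DESeq2 called 173. The count was 0 without siNT library 3, siBAX/BAK library 1, 3 or 4 or siBAX/BAK A/S library 2, 628 without siNT A/S library 1 and 1593 without siNT library 2; the list count was 11 without siNT A/S library 1, 3 without siNT A/S library 2 or siBAX/BAK library 3 and 2 without siNT A/S library 3. ARRDC4 was lost too without siBAX/BAK A/S library 1 or 4 (edgeR adjusted p = 0.0725 and 0.0673), and without siNT library 2 only the heat shock list kept its call. Cells and library kind differ here as well.

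Across backgrounds that share no library, PC9 A/S and knockout A/S had 671 genes called in the same direction (204 expected, 81 opposite; r of 0.282 across genes) and PC9 A/S and the libraries labelled siBAX/BAK 124 (24.7 expected, 14 opposite; r of 0.119). The latter and the knockout had 427 (117 expected, 69 opposite; r of 0.0950). With siNT the overlap was 0 by edgeR and 1 by DESeq2, with r of 0.209 across genes.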

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

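The patterns weighed below and their tests were chosen after the results were seen, except the count with the profile share as a covariate and the tests of the knockout against PC9, which were set before their values were computed.

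The libraries labelled siBAX/BAK differed from every other PC9 group, in 17 of 19 epithelial genes and with r of 0.622 against PC9 DMSO. Library kind was excluded as the cause, since the knockout libraries of the same kind had r of 0.897. With the knockout label taken as given, loss of BAX and BAK was excluded too, since there only 1 of the 19 genes lay below 25% of its PC9 DMSO level. Whether other cells stand under this label was left open. An r below that of HT29 DMSO (0.751) goes with it, but is the pattern itself and does not test it. A genotype call from reads would, and was not made here.

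Few genes were called in the siNT and siATF4 set, 11 for siATF4 against siNT. With the mitochondrial mRNA share as a covariate the count was 2020 and with the siBAX/BAK-like profile share 106, so both may add to the spread. In 11 of the 12 libraries that profile passed the 0.42% found at most elsewhere, up to 13.9% in siATF4 A/S library 3. The 0% of siATF4 A/S library 1 rests on few counts and does not show absence. The HT29 profile passed the 0.31% of the other PC9 libraries in 6 of the 12, up to 0.72%, so whether HT29 reads were mixed in as well cannot be told apart. These explanations are not exclusive, and how any such reads came in was not tested.

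A/S called 6285 genes in the knockout and 1193 in PC9, yet the root mean square log2 effect, corrected for its error, was 0.259 and 0.495, a ratio of 0.523 (0.457 to 0.597 with a library left out). The knockout effect was thus not larger, but may be broader, and library kinds differ. The biological coefficient of variation was 4.51 times higher in PC9 (0.158 against 0.0350), so spread between libraries is a likely part of it. In fits of 2 groups the knockout count was 7522 with all 4 libraries, 6857 with libraries 1 to 3 and 5824 (5761 to 5878 in 10 draws) with these thinned to the PC9 totals, against 4098 for PC9. Fewer and shallower libraries thus lowered the count, but draws from the same libraries cannot tell if that suffices.

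Of 88 tests for a library far from the others of its group of 4, 6 passed, where chance alone passes about 1 in 20. TRIB3 stood at 18.21 CPM in siBAX/BAK library 3 (others 20.09 to 20.33) and MKI67 at 418.8 in siBAX/BAK A/S library 3 (307.5 to 325.7). In the knockout, library 1 had 23830 genes detected (25620 to 25980) and ATF4 at 265.9 (277.6 to 278.7), and library 3 had 97.41% of counts in protein-coding genes (97.54% to 97.56%). ATF3 stood at 19.42 in knockout A/S library 4 (21.72 to 22.15).

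The A/S effects differed between groups, by edgeR tests of the difference. Between the knockout and the libraries labelled siBAX/BAK 2814 genes differed, with ATF4 at 0.27, DDIT3 0.98, ATF3 2.32, TRIB3 0.43, ASNS 0.31, CHAC1 1.04, CDKN1A 1.43 and DUSP6 -0.61. Between HT29 and PC9 7051 genes differed. Higher in HT29 were ATF4 by 1.12, DDIT3 1.88, ATF3 3.65, TRIB3 2.56, ASNS 2.21, CHAC1 2.01, MCL1 1.76 and CDKN1A 3.16, and BOK at -0.56, BCL2L1 at -0.38, DUSP6 at -0.41 and MKI67 at -1.09 were lower. Between the knockout and PC9 5328 genes differed, with ATF3 at 1.54. Lower in the knockout were ATF4 at -0.38, DDIT3 -0.73, TRIB3 -0.61, ASNS -1.42, CHAC1 -2.21, BCL2L1 -0.67, MCL1 -0.35, DUSP6 -0.76 and MKI67 -0.89. Between the libraries labelled siBAX/BAK and siNT 3 genes differed.

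ERCC spike-in shares lay above the range of the controls in every library of 4 treated groups, on average 0.706% with erlotinib and 1.10% with paclitaxel (DMSO 0.129% to 0.313%), and 2.96% with irinotecan and 0.407% with A/S in HT29 (DMSO 0.135% to 0.305%). With A/S in PC9 the mean was 0.105%, but this rested on library 2 with 0%. Libraries 1 and 3, at 0.16% and 0.155%, lay within the DMSO range.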

How the results depend on the processing

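The siATF4 set alternatives based on mitochondrial mRNA and on the profile share, and the use of protein-coding genes only, were chosen only after seeing the results; all others were fixed before the data were examined. The cause of a changed count was not tested unless stated.

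Counts of changed genes stayed within 1.5 times of those reported under every alternative for paclitaxel, irinotecan, vemurafenib and A/S in HT29, the comparisons of paclitaxel, irinotecan and vemurafenib with A/S, A/S in the knockout, and the differences HT29 minus PC9, knockout minus PC9 and knockout minus siBAX/BAK. For erlotinib against DMSO the 8329 genes became 5188 in a fit of only the 2 groups compared, and ranged from 5111 without DMSO library 2 to 12476 without erlotinib library 3. For A/S in PC9 the 1193 became 2259 by DESeq2 and 4098 in a fit of the 2 groups, and ranged from 408 without A/S library 2 to 771 without A/S library 3. Erlotinib against A/S went from 7703 to 4133 in a fit of the 2 groups, and from 5570 without A/S library 1 to 11749 without erlotinib library 3.

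In siNT cells A/S gave 0 genes by edgeR, 4 by DESeq2, 2 with the mitochondrial mRNA share as a covariate and 609 with libraries over 10% mitochondrial mRNA left out. For siATF4 against siNT the 11 genes became 55 with no low-count filter, 528 by DESeq2, 0 in a fit of the 2 groups, 4724 with those libraries left out, 2020 with the mitochondrial share and 106 with the profile share as a covariate, and 0 without siATF4 library 1 to 145 without siNT library 2. In siATF4 cells A/S gave 0 genes, and 1 by DESeq2 or with the mitochondrial share. With A/S in both arms siATF4 gave 3 genes, 25 with no low-count filter, 0 with replicate number as a block, 936 by DESeq2, 0 in a fit of the 2 groups, 3955 with the mitochondrial mRNA-rich libraries left out, 1769 and 8 with the shares of mitochondrial mRNA and of the profile, and 0 without any 1 library. The difference of the A/S effects gave 0, and 1 by DESeq2 or with the mitochondrial share.

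For siATF4 against siNT the ATF4 change of -1.88 became -1.90 in a fit of the 2 groups, where it was not called, and ranged from -1.96 without siNT library 1 to -1.75 without siNT library 2. With A/S in both arms, -1.73 stayed -1.73 with the block and became -1.71 in a fit of the 2 groups, not called in either, and ranged from -1.88 without siATF4 A/S library 1 to -1.65 without siATF4 A/S library 3, again not called.

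For the libraries labelled siBAX/BAK the 762 genes after A/S became 398 in a fit of the 2 groups and ranged from 504 without A/S library 1 to 778 without A/S library 3; 76.8% of the 762 were higher, while the split was 409 higher to 313 lower with DESeq2 size factors and 249 to 149 in the fit of the 2 groups. The difference between their A/S effect and that of siNT gave 3 genes, 0 with the block, 173 by DESeq2, 1593 with the mitochondrial mRNA-rich libraries left out, 50 with the mitochondrial share, and 0 without siNT library 3 to 1593 without siNT library 2. For knockout minus siBAX/BAK the split of 1325 higher to 1489 lower became 1827 to 1159 with DESeq2 size factors and 1981 to 1251 by DESeq2.

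Counts of called lists changed with the list test. With an estimated correlation they fell from 13 to 0 for erlotinib, 9 to 0 for paclitaxel, 8 to 3 for A/S in PC9, 9 to 0 for erlotinib against A/S and 12 to 0 for paclitaxel against A/S. In HT29 they fell from 15 to 5 for irinotecan, 11 to 7 for vemurafenib and 15 to 9 for vemurafenib against A/S. Elsewhere they fell from 14 to 4 for siBAX/BAK, 16 to 9 for the knockout, 13 to 6 for HT29 minus PC9 and 10 to 3 for knockout minus PC9. By fry the counts were 5 for A/S in PC9, 19 for paclitaxel against A/S, 28 for irinotecan, 27 for vemurafenib, 26 for A/S in HT29, 26 for irinotecan against A/S, 27 for vemurafenib against A/S, 9 for siBAX/BAK and 21 for HT29 minus PC9.

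In the siATF4 set the lists called were 3 for A/S in siNT cells, 9 for siATF4, 6 for A/S in siATF4 cells, 7 for siATF4 with A/S in both arms and 5 for the difference, and all 5 fell to 0 with an estimated correlation; by fry they were 0, 4, 0, 2 and 0. For A/S in siNT cells there were 8 with the mitochondrial mRNA-rich libraries left out, 6 with the mitochondrial share, 6 with the profile share, and from 2 without siNT A/S library 2 to 9 without siNT A/S library 1. For A/S in siATF4 cells they ranged from 2 without A/S library 2 to 9 without A/S library 1. With A/S in both arms there were from 4 without siATF4 A/S library 3 up to 7. The difference had from 1 without siATF4 A/S library 2 to 7 without siNT A/S library 1. For siBAX/BAK minus siNT the 5 lists became 0 with an estimated correlation, 0 by fry, 3 with protein-coding genes only, and from 2 without siNT A/S library 3 to 11 without siNT A/S library 1.

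Of 324 single gene results named, 287 kept their direction and call under every alternative, 23 lost the call in some, 14 gained it in some and 0 reversed. Of 226 single list results 78 kept theirs under all and 3 reversed in some. These 3 were the mitochondrially encoded mRNAs, higher in the tests first made. For A/S in siATF4 cells the list was lower with the mitochondrial mRNA-rich libraries left out (adjusted p = 0.00257) and with the mitochondrial share (adjusted p = 0.316, not called). For siATF4 with A/S in both arms it was lower in the same 2 fits (3.36e-05 and 0.584). The difference of the A/S effects was lower for it with those libraries left out (4.75e-20), with the mitochondrial share (0.299) and with the profile share (0.962). With 1 library left out its adjusted p ranged from 1.04e-05 without siATF4 library 2, still higher, to 0.693 without siNT library 2, where it was lower.

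Shared genes called in the same direction changed with the test and with a limit of 2-fold in both comparisons. A/S and erlotinib in PC9 shared 406, 778 by DESeq2 and 165 at 2-fold, and A/S and paclitaxel 715, 1320 and 317. At 2-fold, erlotinib and paclitaxel shared 3652 in place of 6292, A/S and irinotecan in HT29 1502 in place of 5695, A/S and vemurafenib 1485 in place of 5718, and irinotecan and vemurafenib 3163 in place of 8751. A/S in PC9 and in HT29 shared 778, 1385 by DESeq2 and 257 at 2-fold; PC9 and the knockout 671, 1096 and 41; PC9 and siBAX/BAK 124, 234 and 10. For siBAX/BAK and the knockout 427 became 9 at 2-fold, and for PC9 and siNT 0 became 1 by DESeq2.

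Depth limits most the siATF4 A/S group, where library 1 held 0.88 in units of 1e6 counts and ATF4 itself had 86 counts.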

Other observations

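In the libraries labelled siBAX/BAK, EPCAM stood at 2.83 ± 0.269 CPM against 332 ± 22.6 in PC9 DMSO, KRT8 at 19.2 ± 1.5 against 2645 ± 134, and VIM at 612 ± 17.2 against 19.0 ± 1.19 (SD, n = 4 and 3). IRS4 and LIN28B, chosen after their values were seen, stood at 407 ± 13.0 and 104 ± 7.81, against 0.274 ± 0.052 and 0.0674 ± 0.0297 in PC9 DMSO.

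Each comparison was repeated on other splits of its libraries into groups of the same sizes, a test chosen before its values were seen. With 3 against 3 libraries there are 10 splits, so no count can fall among fewer than 1 in 10. The real split alone gave as many genes as it did for erlotinib, paclitaxel and A/S in PC9, erlotinib and paclitaxel against A/S, irinotecan, vemurafenib and A/S in HT29, irinotecan and vemurafenib against A/S, siATF4, and siATF4 with A/S in both arms: 1 of 10 each. The highest count of another split was 0 in these, except 2469 for erlotinib against A/S, in a split that exchanged erlotinib library 3 with A/S library 3. For A/S in siNT and in siATF4 cells all 10 splits gave at least the real count of 0. In siATF4 cells a split that set the 3 mitochondrial mRNA-rich libraries against the others called 8241 genes, which points to structure among those samples.

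As many lists as called were found in 1 of 10 splits for erlotinib, irinotecan, A/S in HT29 and vemurafenib against A/S, 2 for siATF4, 3 for A/S in siATF4 cells, 4 for vemurafenib and for siATF4 with A/S in both arms, 6 for irinotecan against A/S and 7 for A/S in PC9. It was 8 for paclitaxel, for erlotinib against A/S, for paclitaxel against A/S and for A/S in siNT cells. With 4 against 4 libraries and 35 splits, only the real split gave as many genes or lists after A/S, for siBAX/BAK (762 genes, another split 489; 14 lists, 11) and for the knockout (6285 genes, another split 1; 16 lists, 15).

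For differences of A/S effects 100 splits were drawn that exchange backgrounds within a treatment, so most of them carry the difference between backgrounds. Counts as large came in 100 splits for genes and 55 for lists with siATF4 minus siNT, and in 6 and 15 with knockout minus siBAX/BAK. They came in 2 and 15 with HT29 minus PC9, in 3 and 11 with knockout minus PC9, and in 2 and 71 with siBAX/BAK minus siNT. Other splits called up to 1494, 17005, 14352, 13675 and 15897 genes.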
